A study of Rattus norvegicus with 18 samples.

How the data were processed

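RNA was measured in 18 libraries of primary rat hepatocytes: 3 vehicle controls, 4 exposed to APAP, 3 to CCl4, 4 to TCDD and 4 to TCE, each for 6 h in medium with 0.1% DMSO. Per the labels' protocols, total RNA was extracted with TRIzol, treated to remove DNA and made into libraries with standard Illumina methods. Per the submitters' processing notes, kallisto 0.43 was used, which assigns reads to transcripts and shares reads that match several transcripts among them. The genome build, annotation and read layout are not given in the sources used here.

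Each of the deposited tables lists the same rat transcripts with length, effective length, estimated counts (expected counts that need not be whole) and TPM, as the authors made them with kallisto. The deposited TPM values were checked against estimated counts divided by effective length and differed by at most 0.0011%; they were not used for tests. The identifiers carry no gene names in the deposited tables, and 0 of them matched the rat RefSeq gene table used for names, which has no Ensembl identifiers. Tests were therefore run per transcript, as planned for the case that under 80% of counts could be assigned to genes. The gene lists fixed before the data were examined, and albumin and the cytochromes P450, could not be located and are not analysed here.

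Estimated counts were rounded to whole numbers. Transcripts were filtered with edgeR's filterByExpr, which kept 16473, holding on average 99.8% of counts. All 18 libraries were fitted in 1 model with group as the factor (edgeR 4.0.16, TMM factors, robust quasi-likelihood, in R 4.3.3). Each compound was compared with the control, the 4 compounds were compared in a joint test on 3 degrees of freedom, and pairs of compounds were compared in the same fit. A transcript was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the tested transcripts of a comparison. Standard errors were derived from the log2 fold change and the F statistic. Transcripts were named by a rule fixed before the data were examined: past the threshold, a mean of at least 5 CPM in either group, no overlap between the libraries of both groups, and the largest log2 fold changes. The number was lowered to 2 per direction and comparison because no names could be given, and the parts of the rule that need names were not applied. Shares of counts were compared with exact two-sided permutation tests, and shares of transcripts by length or abundance with Fisher's exact test.

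Total estimated counts were 6563387 in TCDD replicate 1 and 9280367 to 11479466 in the other 17 libraries. A fold against a group with 0 counts was computed against a floor of 3 counts in each library of that group and covers counting error only. Of the tested transcripts, 6454 (39.2%) had whole-number counts in all 18 libraries within a tolerance of 0.000001. The others include shared reads, so similar transcripts can trade counts. Of the transcripts named below, only ENSRNOT00000028793.6, ENSRNOT00000028490.2 and ENSRNOT00000009817.4 had whole-number counts in all libraries. Identical values in all libraries were found for 4497 transcripts in 534 sets, of which 124 were tested; values of such transcripts are uncertain. Replicates differed by more than sampling noise in each pair, so each library was counted once.

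The test was run on simulated counts with 200 transcripts changed and 15630 tested. In the simulated TCE comparison, 13.3%, 55.6% and 72.1% of transcripts changed by 1.5, 2 and 4-fold were recovered, with 3 false calls. In the simulated CCl4 comparison, 5.26%, 18.8% and 75.0% were recovered, with 8 false calls. Each simulated transcript was drawn on its own around the control mean, without differences that run through a whole library. These false calls and recovered shares therefore do not cover such differences in the real libraries.

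Alternatives chosen before the data were examined were DESeq2 size factors in edgeR, DESeq2 1.42.0, limma 3.58.1 voom with sample weights, other low-count filters, effective length offsets, a replicate block by the number in the title or in the deposited table's name, a fit of the compared groups alone, thresholds of 0.01 and 0.1, and each replicate left out. Chosen after seeing the data were identical transcripts collapsed to 1, scaling to total counts, removal of each library's trend with transcript length, and leaving out TCDD replicate 1 from the comparisons of the other compounds or together with the length trend.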

Results

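Primary rat hepatocytes, liver parenchymal cells taken from the animal and kept in culture, were exposed for 6 h to 1 of 4 compounds or to the 0.1% DMSO vehicle alone. The compounds were acetaminophen (APAP, an analgesic toxic to the liver at high dose) at 3 mM, carbon tetrachloride (CCl4, a solvent; its dose is not given in the sources used here), the dioxin TCDD (a ligand of the aryl hydrocarbon receptor) at 1 nM and trichloroethylene (TCE, an industrial solvent) at 1 mM. The doses were described as below overt toxicity, with little cell death but lower albumin output and higher cytochrome P450 activity. The treatment protocol that says so does not name CCl4, so this description may not cover it. RNA was sequenced from 18 libraries: 3 for the control, 4 for APAP, 3 for CCl4, 4 for TCDD and 4 for TCE. The labels do not say whether replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Values are given per transcript, by identifier, because the files do not pair identifiers with gene names.

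Total estimated counts ranged from 9280367 to 11479466 in 17 libraries and were 6563387 in TCDD replicate 1. That library also listed 27416 transcripts with a count above 0, against 19151 to 19801 in the other 17 libraries. Its log2 CPM correlated with those of the other libraries, across transcripts, at 0.830 to 0.866. The first principal component held 35.3% of the variance and separated the 4 APAP libraries from the rest, and the second held 16.1% and separated TCDD replicate 1. Counts of changed transcripts are therefore given with and without that library. In all, 16473 transcripts passed the low-count filter and were tested.

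**Figure D1:**
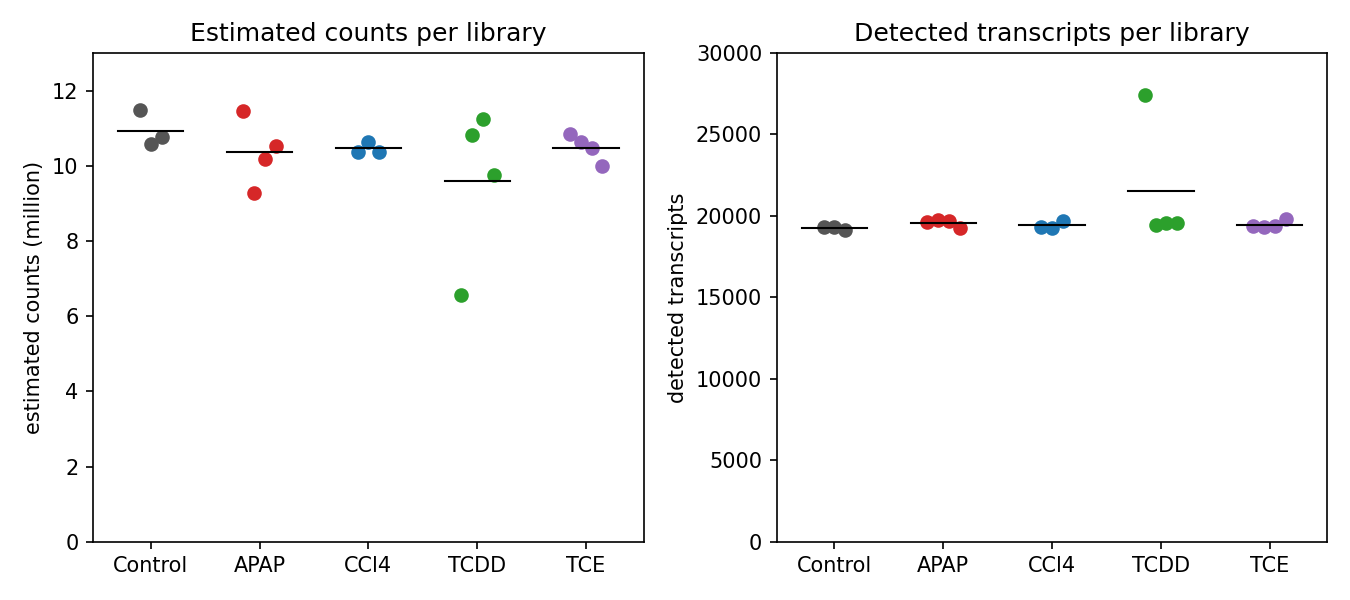
Total estimated counts (left) and number of transcripts with a count above 0 (right) for each library, by group; points are libraries and lines are group means. TCDD replicate 1 had 6563387 counts and 27416 detected transcripts, the lowest and highest of the 18 libraries.

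**Figure D2:**
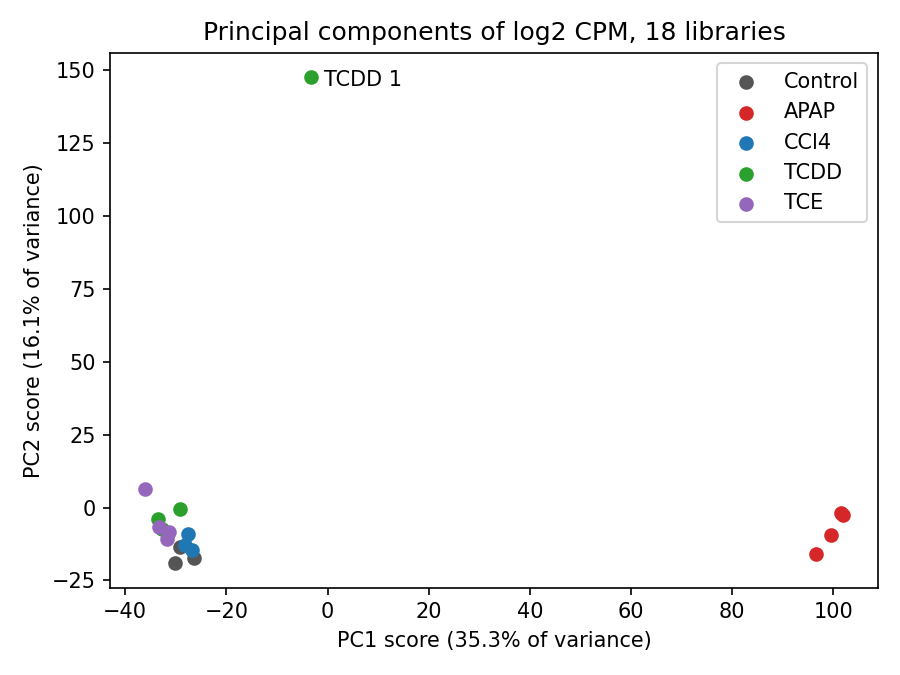
Scores of the 18 libraries on the first and second principal components of log2 CPM, colored by group, each axis with its percent of variance. The 4 APAP libraries lie apart on the first component (35.3%) and TCDD replicate 1 on the second (16.1%).

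The comparison of APAP with the control asked what the known liver toxicant changed at a dose with little cell death. APAP changed 7556 of the 16473 transcripts, 3224 higher and 4332 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 3092 of them by over 2-fold. Abundant transcripts mostly rose: 71 of the 100 most abundant rose and 2 fell, while of the 11473 least abundant, 1424 rose and 3108 fell. Abundance was ranked by the mean CPM of all 18 libraries, APAP included. Transcripts that rose held 48.7% ± 2.02 of all counts in the control (SD, n = 3) and 63.3% ± 0.969 with APAP (SD, n = 4). Those that fell held 16.2% ± 0.967 and 7.24% ± 0.392. Both sets were picked by direction in these same libraries, so the direction of these shifts follows from the choice and is not a separate result. The most abundant transcript, the same in all 18 libraries, rose from 5.64% ± 0.214 of counts (n = 3) to 8.25% ± 0.248 (n = 4), with no overlap between the groups (exact two-sided permutation test, p = 0.0571, the smallest that 3 against 4 libraries allow; adjusted p = 0.229 over 8 tests).

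ENSRNOT00000028780.4 had 0 counts in the 3 control libraries and 54.4 ± 11.6 CPM (SD, n = 4) with APAP, at least 205-fold higher against a floor of 3 counts in each library (edgeR adjusted p = 7.33e-07). ENSRNOT00000087926.1, also at 0 in the control, reached 16.2 ± 4.82 CPM (SD, n = 4), at least 61.0-fold higher (edgeR adjusted p = 0.00489). In the other direction, ENSRNOT00000034097.7 had 7.00 ± 1.53 CPM (SD, n = 3) in the control and 0 counts in the 4 APAP libraries, at least 20.0-fold lower (edgeR adjusted p = 1.88e-06). ENSRNOT00000005325.7 had 6.87 ± 2.71 CPM (SD, n = 3) in the control and 0 counts with APAP, at least 19.7-fold lower (edgeR adjusted p = 0.00117; limma voom with quality weights, adjusted p = 0.102). Outside APAP, ENSRNOT00000005325.7 had 0 counts in TCDD replicate 1 and 12 in TCE replicate 4, against 78 to 121 in the other TCDD and TCE libraries. The 4 transcripts named here lacked whole-number counts, so shared reads can move between them and similar transcripts. Without TCDD replicate 1, APAP changed 8261 transcripts, of which 7523 were shared with the 7556. The balance of directions depended on the scaling: 42.7% of changed transcripts were higher with TMM factors and 19.9% with scaling to total counts alone, which moved the median log2 fold change of all transcripts from -0.04 to -0.35.

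For CCl4 the question was what it changed at its dose, which is not given. CCl4 changed 287 transcripts, 170 higher and 117 lower, 37 of them by over 2-fold. The transcripts that rose held 1.96% ± 0.101 of counts in the control and 2.90% ± 0.0119 with CCl4 (SD, n = 3 each). As with APAP, the direction of this shift follows from how the transcripts were picked. ENSRNOT00000083472.1 rose from 14.2 ± 1.70 to 57.6 ± 4.00 CPM (SD, n = 3 each), a log2 fold change of 2.02 ± 0.27 (SE; edgeR adjusted p = 0.0012), and stood at 73.4 ± 9.01 CPM with APAP (SD, n = 4). ENSRNOT00000092366.1 rose by 1.78 ± 0.39 on the log2 scale (SE; edgeR adjusted p = 0.0304). ENSRNOT00000046529.5 fell by 1.43 ± 0.28 on the log2 scale (SE; edgeR adjusted p = 0.0196) and ENSRNOT00000002020.6 fell by 1.38 ± 0.24 (SE; edgeR adjusted p = 0.0092). ENSRNOT00000092366.1 and ENSRNOT00000046529.5 also passed, in the same direction, with APAP (edgeR adjusted p = 6.26e-06 and 0.000886) and TCDD (0.0301 and 0.0449), and ENSRNOT00000002020.6 with TCE (0.0483). ENSRNOT00000092366.1 and ENSRNOT00000046529.5 no longer passed without control replicate 1 (edgeR adjusted p = 0.177 and 0.113), control replicate 2 (0.181 and 0.138), CCl4 replicate 1 (0.106 and 0.0898) or CCl4 replicate 2 (0.155 and 0.121), nor did ENSRNOT00000046529.5 without CCl4 replicate 3 (0.055). ENSRNOT00000002020.6 no longer passed without control replicate 2 (edgeR adjusted p = 0.0504) or CCl4 replicate 2 (0.0694). With only the CCl4 and control libraries in the fit, 433 transcripts changed, 192 of them among the 287, and these 3 did not pass (edgeR adjusted p = 0.0603, 0.0809 and 0.0688). DESeq2 called 949, limma voom 4287, and edgeR without a low-count filter 122. The count moved with single libraries: it was 48, 56 and 985 without control replicates 1, 2 and 3, 68, 51 and 64 without CCl4 replicates 1, 2 and 3, and 670 and 491 without TCDD replicates 1 and 4, which enter through the shared fit. With scaling to total counts 74.4% of 117 changed transcripts were higher, against 59.2% with TMM factors.

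TCDD changed 717 transcripts, 245 higher and 472 lower, 61 of them by over 2-fold. Without TCDD replicate 1 it changed 273, of which 232 were shared with the 717, 109 higher and 164 lower. ENSRNOT00000072532.2 and ENSRNOT00000081194.1, of 135 and 180 bases, rose by 4.28 ± 0.90 and 4.11 ± 0.92 on the log2 scale (SE; edgeR adjusted p = 0.0258 and 0.0294), and by 3.24 and 3.36 without TCDD replicate 1 (edgeR adjusted p = 0.0423 and 0.0498). That library had 14.1 and 13.1 CPM, against 1.28 to 4.40 and 1.28 to 6.60 CPM in TCDD replicates 2 to 4. The 2 transcripts had TCDD means of 5.51 and 5.87 CPM, which reached the 5 CPM minimum for naming only through that library. They had 9 and 11 counts in the 3 control libraries together, and neither had whole-number counts in all libraries. Both were shorter than the gap between length and effective length of the longest transcript, 185 to 190 bases in the TCDD libraries. The counts of these 2 transcripts are therefore uncertain. Their log2 fold changes were 2.88 and 3.01 with CCl4 and 3.00 and 2.92 with TCE, which did not pass (edgeR adjusted p from 0.0935 to 0.115). ENSRNOT00000079506.1 fell by 1.60 ± 0.38 and ENSRNOT00000081604.1 fell by 1.52 ± 0.36 on the log2 scale (SE; edgeR adjusted p = 0.0364 and 0.0343), and neither passed without TCDD replicate 1 (edgeR adjusted p = 0.0637 and 0.0674) or TCDD replicate 4 (0.0623 and 0.0598). Both also fell with APAP (edgeR adjusted p = 0.0182 and 0.0122). These 4 transcripts did not pass without control replicate 1 (edgeR adjusted p from 0.153 to 0.179) or control replicate 2 (0.167 to 0.227). The count was 0 without control replicate 1 or control replicate 2, 1778 without control replicate 3, and 1246, 1155 and 323 without TCDD replicates 2, 3 and 4. Libraries outside the comparison moved it through the shared fit: it was 236, 261 and 257 without CCl4 replicates 1, 2 and 3, 442, 361 and 297 without TCE replicates 1, 2 and 3, and 367 and 384 without APAP replicates 1 and 3. It was also 0 when the fit held only the TCDD and control libraries, and 279 with the length trend of each library removed, 1708 with DESeq2 and 3592 with limma voom. With scaling to total counts 81.6% of 310 changed transcripts were higher, against 34.2% with TMM factors.

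TCE changed 191 transcripts, 89 higher and 102 lower, 13 of them by over 2-fold. ENSRNOT00000028793.6 rose from 1.65 ± 0.209 CPM (SD, n = 3) to 5.12 ± 0.979 CPM (SD, n = 4), a log2 fold change of 1.63 ± 0.32 (SE; edgeR adjusted p = 0.0298). ENSRNOT00000028490.2 rose from 16.6 ± 2.00 CPM (SD, n = 3) to 38.9 ± 5.15 CPM (SD, n = 4), a log2 fold change of 1.23 ± 0.23 (SE; edgeR adjusted p = 0.0267), and stood at 7.08 ± 0.805 CPM with APAP (SD, n = 4). ENSRNOT00000028793.6 and ENSRNOT00000028490.2 also rose with CCl4 (edgeR adjusted p = 0.0438 and 0.0306) and TCDD (0.0214 and 0.0331), and ENSRNOT00000009817.4 also fell with TCDD (0.0358). ENSRNOT00000009817.4 fell by 1.15 ± 0.26 and ENSRNOT00000090763.1 fell by 1.12 ± 0.23 on the log2 scale (SE; edgeR adjusted p = 0.0482 and 0.0361). These 4 transcripts did not pass without control replicate 1 (edgeR adjusted p from 0.164 to 0.231), control replicate 2 (0.197 to 0.327), TCE replicate 1 (0.0522 to 0.117), TCE replicate 2 (0.0548 to 0.124) or TCE replicate 3 (0.0814 to 0.131). The count was 0 without control replicate 1, control replicate 2 or TCE replicate 3, 10 without TCE replicate 2, 61 without TCE replicate 1, and 1157 without control replicate 3. Libraries outside the comparison moved it through the shared fit: it was 779, 97 and 356 without TCDD replicates 1, 3 and 4, 71, 100 and 72 without APAP replicates 1, 2 and 3, and 66, 64 and 71 without CCl4 replicates 1, 2 and 3. It was 16 when the fit held only the TCE and control libraries, with 3 of these among the 191. With the length trend of each library removed it was 61, and there ENSRNOT00000028490.2 and ENSRNOT00000009817.4 did not pass (edgeR adjusted p = 0.0597 and 0.0612). DESeq2 called 1034 and limma voom 4679. With scaling to total counts 93.9% of 440 changed transcripts were higher, against 46.6% with TMM factors.

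**Figure D3:**
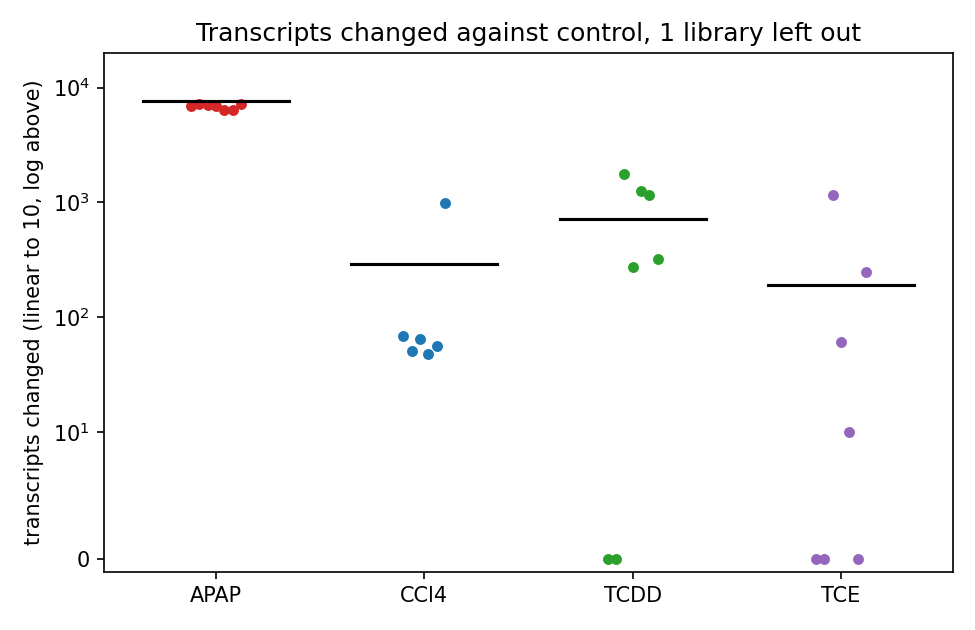
Number of transcripts changed against the control for each compound; lines give the count from all 18 libraries and points the count with 1 library of the compound or control left out, on an axis that is linear up to 10 and logarithmic above. The APAP counts stay between 6377 and 7248, while the TCDD and TCE counts range from 0 to 1778 and from 0 to 1157.

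Direction followed transcript length in the 4 comparisons with the control. Among changed transcripts over 2000 bases, 28.5% were higher with APAP, 35.9% with CCl4, 10.5% with TCDD and 14.9% with TCE; among shorter ones the values were 60.3%, 91.7%, 76.4% and 82.2%. The rank correlation of log2 fold change with length, across transcripts, which are not independent replicates, was -0.219 for APAP, -0.281 for CCl4, -0.226 for TCDD and -0.308 for TCE. Between pairs of compounds it ranged from -0.108 to 0.0129.

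**Figure D4:**
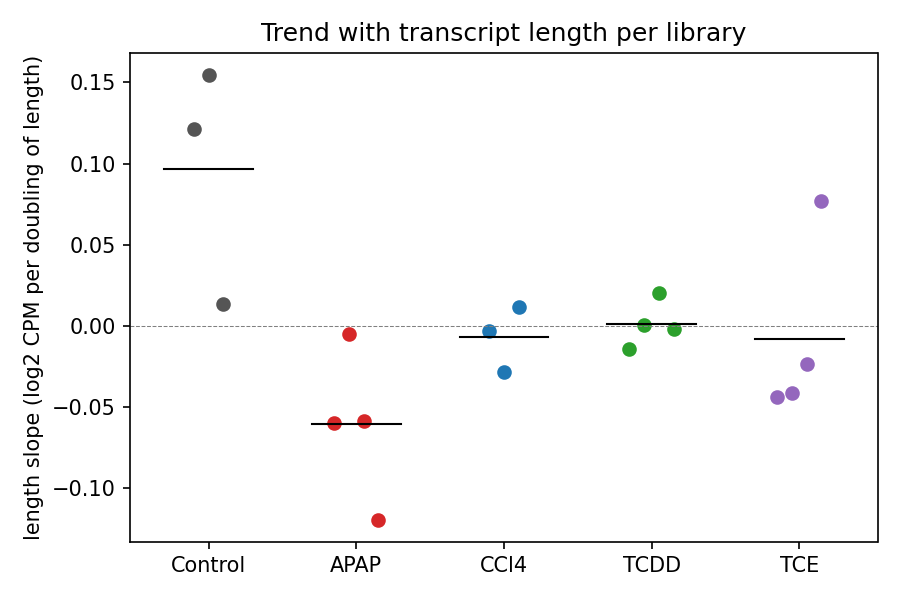
Slope of each library's log2 CPM, as deviation from the mean of the 18 libraries, on log2 transcript length, by group; points are libraries and lines are group means. Control replicates 1 and 2 have the highest slopes (0.12 and 0.15), followed by TCE replicate 4 (0.08).

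Compounds were also compared with each other, in contrasts that leave out the control means, within the fit of all 18 libraries. Across the 4 compounds 8352 transcripts differed (edgeR quasi-likelihood test on 3 degrees of freedom), and 8470 without TCDD replicate 1. APAP differed from CCl4 in 7398 transcripts, from TCDD in 8295 and from TCE in 7884. CCl4 differed from TCDD in 183 transcripts, 148 of them higher with CCl4, and from TCE in 151, 100 of them higher with CCl4. Without TCDD replicate 1 these counts were 8119, 8266 and 8598 for APAP, 161 for CCl4 against TCDD and 307 for CCl4 against TCE, 210 of them higher with CCl4. ENSRNOT00000083472.1 was higher with CCl4 than with TCE by 1.99 ± 0.25 on the log2 scale (SE; edgeR adjusted p = 0.000563). For TCDD against TCE the edgeR quasi-likelihood test called 0 transcripts, with 1262 at an unadjusted p under 0.05. Without TCDD replicate 1 it called 0, with 412. If nothing differed, a share of about 0.05 of the tested transcripts would fall there, which is fewer than 1262 and more than 412. The 95% interval of the difference between TCDD and TCE lay within 1 log2 unit of 0 for 70.7% of transcripts. It lay wholly beyond 1 unit for 102 (26 without TCDD replicate 1). These intervals were not adjusted for the number of transcripts. Doses were not matched between compounds.

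Changed in the same direction by all 4 compounds were 17 transcripts, 9 higher and 8 lower, and 43 without TCDD replicate 1. Of the 9 higher, 8 were of up to 2000 bases, and of the 8 lower, 7 were over 4000 bases, against 45.1% and 17.6% of tested transcripts. With the length trend of each library removed, the count was 2, with 0 higher, and 14, with 8 higher, where TCDD replicate 1 was also left out, while DESeq2 gave 145 and limma voom 1190. These comparisons share the control libraries, which were not split because a part would hold 1 library. TCDD and TCE had 66 transcripts higher in both, 84 lower in both and 0 in opposite directions, where independent lists would share 1.32 and 2.92. Among 11331 abundant transcripts their log2 fold changes correlated at 0.628, with a covariance of 0.132. In 20 simulations of unchanged groups that shared simulated controls, the means were 0.576 and 0.0537. Each simulation redrew all libraries around the control means, transcript by transcript. It held no difference that runs through a whole library, such as the length trend. It therefore cannot show whether covariances above the simulated ones, here or below, exceed what the real controls give. Part or all of the excess may come from the shared controls. APAP and TCE had 56 transcripts higher in both, 22 lower in both and 50 in opposite directions, where independent lists would share 17.4 and 26.8. Without TCDD replicate 1 the pair had 199, 144 and 156, where independent lists would share 76.2 and 125, and TCDD and TCE had 96 higher in both, 133 lower in both and 0 in opposite directions. With all 18 libraries, the log2 fold changes of APAP and TCE correlated at 0.223, against a simulated mean of 0.574, with a covariance of 0.0695 against 0.0540. For CCl4 and TCDD the correlation was 0.501 against a simulated 0.530, and for CCl4 and TCE 0.699 against 0.540. For APAP with CCl4 and with TCDD it was 0.282 and 0.267, against 0.531 and 0.570. Their covariances were 0.115, 0.0934, 0.0955 and 0.143 in the same order, against simulated means of 0.0532, 0.0546, 0.0539 and 0.0534. The simulated groups held no changes, whereas real changes by APAP add spread to its log2 fold changes and lower a correlation. Correlations below the simulated ones therefore cannot show that compounds were less alike than unchanged groups. Without TCDD replicate 1 the correlation was 0.841 for TCDD and TCE and 0.712 for CCl4 and TCDD, against simulated means of 0.546 and 0.505, with covariances of 0.105 and 0.0969 against 0.0340 and 0.0344. The count of 17 was 0 without control replicate 1, control replicate 2, TCE replicate 2 or TCE replicate 3, and 314 without control replicate 3; without each other APAP, CCl4, TCDD or TCE library it lay between 2 and 43.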

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

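All tests of explanations and the splits of samples given here were set after the results were seen. Gaps between 1 library and the rest of its group of 4 were checked in 31 sets of values, of which 4 stood out; chance gives about 5%. TCDD replicate 1 stood apart with 27416 detected transcripts, against 19470 to 19592 in TCDD replicates 2 to 4. It also held 2.65% of counts in tested transcripts of identical values, against 0.351% to 0.532%. Most of its 2.65% came from 2 sets, of 2 and 5 transcripts. Each member of the first set held 6679 CPM in TCDD replicate 1 and 258 to 873 CPM in TCDD replicates 2 to 4. For the second set the values were 1952 CPM and 87.2 to 228 CPM. TCE replicate 4 stood apart in its length slope, 0.0768 against -0.0438 to -0.0237 in the other TCE libraries. ENSRNOT00000009817.4 had 51.1 CPM in TCE replicate 4 and 33.1 to 34.9 CPM in the other TCE libraries.

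In TCDD replicate 1, 4169 of the 5634 transcripts at 0 in the other 17 libraries had counts (74.0%). Lower depth would give fewer detected transcripts, not the 27416 found with 6563387 estimated counts, and exposure to TCDD would raise the number in TCDD replicates 2 to 4, which reached 19592. Reads spread thinly over all transcripts, as from genomic DNA or unspliced RNA, may be the source, and this stays open. At least 59.6% of the transcripts at 0 elsewhere were detected in each of 5 length classes. The share rose from 59.6% under 500 bases to 82.0% at 500 to 1000. It then fell to 73.3% at 1000 to 2000 and 72.6% at 2000 to 4000, unlike an even spread, and was 76.3% above. Counts rose with length (rank correlation 0.332). Median reads per kb fell from 5.44 in the shortest class to 1.86 in the longest. That fall cannot decide, because 1 read on a short transcript already gives a high value per kb. RNA of other cells was not tested, since markers could not be located.

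Transcripts with identical values held 2.62% ± 0.610 of counts in the control (SD, n = 3), 0.553% ± 0.0439 with TCE (SD, n = 4) and 0.469% ± 0.102 in TCDD replicates 2 to 4. The difference lay mainly in the 2 sets of 2 and 5 transcripts described above, not in the class as a whole. Each member of the first set held 5148 to 8970 CPM in the control libraries and 676 to 1012 CPM with TCE. For the second set the ranges were 1358 to 2124 CPM and 198 to 286 CPM. Exposure to TCDD or TCE stays open, because 1 of the 8 libraries, TCDD replicate 1, lay in the control range, and that library stands apart in other ways. Variation between libraries unrelated to the compound may also account for it, and stays open too: the share differed 5.06-fold between the highest and lowest APAP library but 1.74-fold within CCl4 and 1.60-fold within the control, against 4.73-fold between the control and TCE means, and the TCE libraries spanned 0.503% to 0.610%. TCE against the control gave p = 0.0571 in an exact permutation test, the smallest possible (adjusted p = 0.229 over 8 tests).

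Long transcripts were lower and short ones higher in each comparison with the control. Different fragment lengths, as far as effective lengths carry them, do not account for this. With effective length offsets the rank correlation nearest to 0 was still -0.219, farther from 0 than in any pair of compounds (-0.108). The offsets moved the correlations little (for TCE from -0.308 to -0.320), so other effects of fragment length stay open. Length slopes averaged 0.0965 in the control (n = 3) and -0.0193 in the 15 exposed libraries (exact two-sided permutation test over 816 splits, p = 0.00735, for a measure chosen after seeing the trend). Exposure to the compounds stays open, with 1 control library, replicate 3, within the range of the exposed libraries. Variation between libraries that follows length also stays open: of the splits other than the real one, that with the largest slope difference called as many transcripts as the real split in 1 of 4 comparisons, TCE (1147 against 191), but 4652 against 7556 for APAP, 1 against 287 for CCl4 and 0 against 717 for TCDD.

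Other splits of the samples bear on whether chance can be excluded. For APAP, 1 of the 35 splits, the real one, reached 7556 transcripts and the highest other gave 4652, so chance is excluded at 0.05. For TCDD, 2 of the 35 splits reached 717, and chance is not excluded. The other gave 976, with TCDD replicate 2 beside the 3 controls, against TCDD replicates 1, 3 and 4. That split kept the controls together. For TCE, 2 of the 35 splits reached 191, and chance is not excluded. The other, control replicate 3 with TCE replicates 1 to 3 against the rest, gave 1147. That split points to a structure of the samples that the groups do not follow. Its difference in length slope (-0.141) was larger than that of the real split (-0.105). For CCl4 the 10 splits are too few for a share under 0.05; the real split gave 287 and the highest other 1. For the difference among compounds, 1 of 100 splits, the real one, reached 8352. Chance is thus excluded at 0.05 only for the case that no compound differed from another. The highest other gave 7579, from a split that kept the 4 APAP libraries together and mixed CCl4, TCDD and TCE. The splits therefore cannot show whether CCl4, TCDD and TCE differed from each other. For transcripts changed in the same direction by all 4 compounds, 2 of 100 splits reached 17; the other gave 1380, with 3 APAP libraries in place of the control. These splits scatter the APAP libraries over the groups, so they bear only on whether no compound changed anything, and chance is not excluded for the TCDD and TCE calls that the 17 belong to.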

How the results depend on the processing

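Chosen after seeing the data were the collapse of identical transcripts, scaling to total counts, removal of the length trend, and the counts without TCDD replicate 1 for APAP, CCl4 and TCE. The counts for APAP and for the difference among compounds stayed within 1.5 times of 7556 and 8352 under each alternative. Of 324 alternative values of the named transcripts, 245 kept their side of the threshold, 79 kept their direction but no longer passed, and 0 reversed. The 79 were spread unevenly. Only 1 was of a transcript named for APAP, ENSRNOT00000005325.7. For the other compounds the number per transcript ran from 0 (ENSRNOT00000083472.1, CCl4) to 12 (ENSRNOT00000009817.4, TCE). Named transcripts were chosen for no overlap between the libraries of both groups, so leaving out 1 library could hardly reverse them. A setting that filtered out a transcript or gave it no adjusted p gave no value. The cause was not tested for the counts below unless fewer samples or another threshold sets it. Where an edgeR count at adjusted p under 0.05 was 0, 2155 to 3704 transcripts for TCDD and 1524 to 2226 for TCE had an unadjusted p under 0.05. The gene lists fixed beforehand were not run under any setting.

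With DESeq2 size factors in edgeR, TCE changed 108 transcripts and 9 changed in the same direction with all 4 compounds. DESeq2 gave 949 for CCl4, 1708 for TCDD, 1034 for TCE and 145 in the same direction. Limma voom with quality weights gave 4287, 3592, 4679 and 1190, and no filter on low counts gave 122, 266, 95 and 4, in the same order. The voom weights were 3.35, 0.863 and 0.41 for control replicates 1 to 3, so its control means leaned on replicate 1. With only the compared groups the counts were 433, 0, 16 and 0. At a threshold of 0.01 they were 51, 0, 0 and 0, and at 0.1 they were 700, 2193, 706 and 82. Scaling to total counts gave 117 for CCl4, 310 for TCDD and 440 for TCE. With the length trend removed TCDD changed 279, TCE 61, and 2 changed in the same direction; with TCDD replicate 1 also left out, CCl4 changed 488, TCDD 160 and TCE 362, and 14 changed in the same direction.

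The replicate numbers share only a number: deviations of same-numbered libraries correlated at -0.0108 on average by the title and -0.0183 by the deposited table's number, and 5 and 4 of 18 libraries correlated best with their own number. The replicate block by title gave 0 for TCDD, 18 for TCE and 0 in the same direction; by the table's number it gave 106 for CCl4, 293 for TCDD, 95 for TCE and 3 in the same direction.

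With 1 replicate of the compared groups left out, counts ranged from 6377 to 7248 for APAP (8261 without TCDD replicate 1), 7321 to 8718 among compounds, and 0 to 314 in the same direction. For CCl4 they ranged from 48 to 985, with 48 and 56 without control replicates 1 and 2, 985 without control replicate 3, 68, 51 and 64 without CCl4 replicates 1 to 3, and 670 without TCDD replicate 1. For TCDD they ranged from 0 (without control replicate 1 or 2) to 1778 (without control replicate 3), with 273, 1246, 1155 and 323 without TCDD replicates 1 to 4. For TCE they ranged from 0 (without control replicate 1, control replicate 2 or TCE replicate 3) to 1157 (without control replicate 3), with 61 and 10 without TCE replicates 1 and 2, and 779 without TCDD replicate 1. Leaving out 1 library outside the comparison gave 200 to 670 for CCl4, 236 to 990 for TCDD and 64 to 779 for TCE. TCDD replicate 1 had the lowest total of estimated counts, 6563387.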
